A study of Bacillus subtilis PY79 with 81 samples.

How the data were processed

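The series holds 81 libraries of Bacillus subtilis PY79, 65 of them Hi-C contact maps and 16 ChIP-seq or input tracks. The 16 tracks are 7 SMC ChIP libraries, 1 ParB ChIP library and 8 inputs without antibody. Every combination of assay, strain, inducer and time in the labels is represented by 1 library, so there are 81 groups of 1 library and no group has replicates. The ChIP and input labels of BWX5066 read rep2, and the series holds no other replicate of them. Per the labels, cells grew in CH, a rich medium, at 37 °C and were fixed with formaldehyde, and Hi-C used the restriction enzyme HindIII. Strains, parS positions in degrees, array positions, inducers and times were taken from the labels alone.

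Each deposited contact map is a symmetric table of 404 by 404 bins of 10 kb, and its values are a fraction: the contacts of a bin as a share of that bin's total, written by the authors to 4 decimals. Row sums lay close to 1 in every map, which shows that the authors had balanced the maps; the balancing method and the genome build are not given in the sources used here. The main diagonal and its neighbours were listed at 0. The number of read pairs behind a map is unknown, so no counting interval was given for any contact value. Each ChIP or input file holds the deposited coverage signal, a whole number per base over positions 1 to 4033459. Mean coverage was 12.0 for ParB ChIP, 20.2 to 27.5 for the 6 SMC ChIP libraries with SirA, 63.3 for the SMC ChIP library without it and 20.3 to 30.4 for the inputs. The submitters' processing notes name Bowtie2 2.1.0, which aligns reads; filters and the treatment of duplicates are not given in the sources used here. Balancing gives every bin the same total, so a gain of contacts at some pixels of a bin lowers its other pixels, and contact values are relative within a map. Coverage was not scaled between libraries in the files.

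Contact maps were divided by the expected contact at the same circular separation in the same map, taken as the mean after removing the highest and lowest 10% of values. The hairpin line of a parS site was read at separations of 60 to 400 kb. The midpoint of the contacting loci was allowed to move in proportion to the separation, with a slope (the tilt) between -0.4 and 0.4 in steps of 0.01, and the site to move by 1 bin. The tilt with the highest mean contact over expected within 1 bin of the line was kept, and the strength is log2 of that mean. Choosing the best line raises the strength where a map has no hairpin, but such readings can still lie below 0. At -94°, 7 maps with no site within 10° and no array, that without parS among them, ran from -1.13 to -0.01. Hairpin divergence is the tilt of the outer site at the higher coordinate minus the tilt of the outer site at the lower coordinate, so that a tilt common to both sites cancels. Contacts along the line between a pair of sites were read within 5 bins of the midpoint, over the 300 kb past 2 times the spacing. Contacts beyond the partner were read within 5 bins of a site's own antidiagonal, over the 200 kb past 2 times the spacing. Contacts joining neighbouring sites were read within 2 bins of each. The background of the midpoint line and of the joining contacts was the mean of the same pixels in the map without parS and 3 maps with 1 site. The strain, or the pair of libraries with matching genotype, was the unit of each Hi-C test. The test of SMC ChIP at parS took the 5 sites of 2 strains as its units; sites of a strain share its libraries and are not independent, so its p-value describes the spread between sites and not between strains. Tests were exact two-sided sign-flip permutation tests, in which every sign assignment is enumerated, with Benjamini-Hochberg adjustment over the 9 Hi-C tests. Such p-values measure the spread between strains, some of which share control maps, and not the spread between cultures of a strain.

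In the ParB time courses, the front was planned as the largest separation up to which contact over the 0 min map stayed above log2 of 0.5 within 4 bins of the antidiagonal, starting at 60 kb. That reading found no front in most maps. A second reading, chosen after the maps were seen, followed the ridge outwards from its strongest point within 600 kb of separation, with the midpoint free within 250 kb of the site and a threshold of 0.5 or 1. The rate per leg is the slope of front/2 on time, with fronts at the far side of the chromosome left out. The (XDS)12 array strains were also described by measures chosen after the maps were seen, hairpin strength at the nearest site and contacts joining the 200 kb on either side of the array. Windows of 100 and 400 kb had been looked at too when the second was chosen, and are given in the closing section.

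Coverage was averaged in 1 kb bins and divided by the library's genome mean. A pseudocount of 0.02, which was not among the choices fixed in advance, was added, and log2 of ChIP over the matching input was taken. Enrichment at a site is the mean over the 20 kb around it. The stretches between sites left out 20 kb beside each site and were compared with flanks of the same total length. The origin to terminus ratio is the mean input coverage within 100 kb of 0° over that within 100 kb of 172°. All parS and array positions in the labels were named, with the 10 bins of 1 kb that had the highest mean SMC enrichment over the 6 libraries with SirA and lay over 100 kb from every labelled parS of those strains, merged when within 3 kb. Degrees were converted to kb from the length of the coverage files. The gene table at hand belongs to another assembly (ASM2352161v1), so no gene names were assigned, and a planned comparison of SMC ChIP over gene lists is not analysed here.

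The hairpin functions were tested on simulated maps. In 30 simulated maps the tilt was found within 0.05 of its true value. Simulated maps without a hairpin had a mean strength of 0.13, against 1.36 with one. A simulated divergence of 0.25 was found as 0.27 ± 0.02 (SD, 10 maps), and traced fronts lay within 10 kb of their true value in 12 maps. Those simulated hairpins kept a constant height and ended abruptly, so the 10 kb does not measure the error for ridges that fade. In the real courses the thresholds of 0.5 and 1 gave fronts as far apart as 1310 and 640 kb (BWX4493, -94°, 15 min). With no effect and 10 values, the exact sign-flip test passed 0.05 in 5.4% of 4000 simulations. The measures, tests and alternatives were chosen before the data were examined, except where the text says otherwise. The alternatives tried were another expected contact, division by the map without parS, wider bands, shorter separations, fixed sites, other front thresholds, other windows and scalings for ChIP, and leaving out each strain in turn. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.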

Results

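SMC condensin complexes are loaded on the Bacillus subtilis chromosome at parS, a short sequence bound by the partition protein ParB, and fold the chromosome by extruding DNA loops. In a contact map, loop extrusion from a parS site appears as a hairpin, a line of contacts between loci at similar distances on either side of the site. The series title names the question of whether complexes loaded at different sites can traverse one another. Strains in a parSΔ9 background, in which parS sites had been deleted, carried 0 to 3 parS sites at labelled positions from -27° to -153° on the left side of the origin at 0°. SirA, an inhibitor of replication initiation, was induced with 1 mM IPTG in most strains. The 65 Hi-C maps comprise 10 strains with 2 or 3 sites after 60 min of SirA, their 10 counterparts without SirA induction, strains with 1 site or none, time points of 90 and 120 min, 5 strains with an (XDS)12 array, 1 strain with additional inducible smc and scpAB, and 18 maps of ParB induction. Each condition had 1 library, so no value below has a replicate error. The sequencing depth of the maps is unknown.

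Input coverage was level between origin and terminus after SirA induction and not before. Coverage at the origin was 3.02 times that at the terminus in uninduced BWX3370, a strain with parS at -1° and no sirA construct, and 2.75 times in BWX4462 before IPTG. In the 6 inputs taken 60 to 120 min after SirA induction the ratio was 0.98 ± 0.07 (SD, n = 6), with a range of 0.91 to 1.11. This difference of level was not tested, as only 2 inputs had no SirA.

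ParB bound both labelled sites of BWX4462 (parS at -27° and -59°). The highest 1 kb bins of ParB ChIP were 3726001 to 3727000, at log2 of 8.90 over input, and 3378001 to 3379000, at log2 of 8.16, against a genome median of -1.37. They lay -4.45 kb and 6.08 kb from the positions computed from the degrees, 3731 kb and 3372 kb. Enrichment above log2 of 1 ran over 15 kb at -27° and 24 kb at -59°. At -59° it reached 15 kb from the maximum towards lower coordinates and 8 kb towards higher ones. ParB coverage averaged 12.0 reads per base, the lowest of the tracks, with a median of 4.

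Maps of strains with a single parS site had hairpins at the labelled position, and the map without parS had none of similar strength there. After 60 min of SirA, lone sites gave hairpin strengths of 1.65 at -59° in BWX4475, 1.58 at -91° in BWX4515 and 1.22 at -94° in BWX4476, as log2 contact over expected. The map without parS, BWX4473, read the same way, gave 0.29, 0.18 and -0.01 at those positions. The lone hairpins leaned towards lower coordinates, with tilts of -0.12, -0.05 and -0.17.

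**Figure D1:**
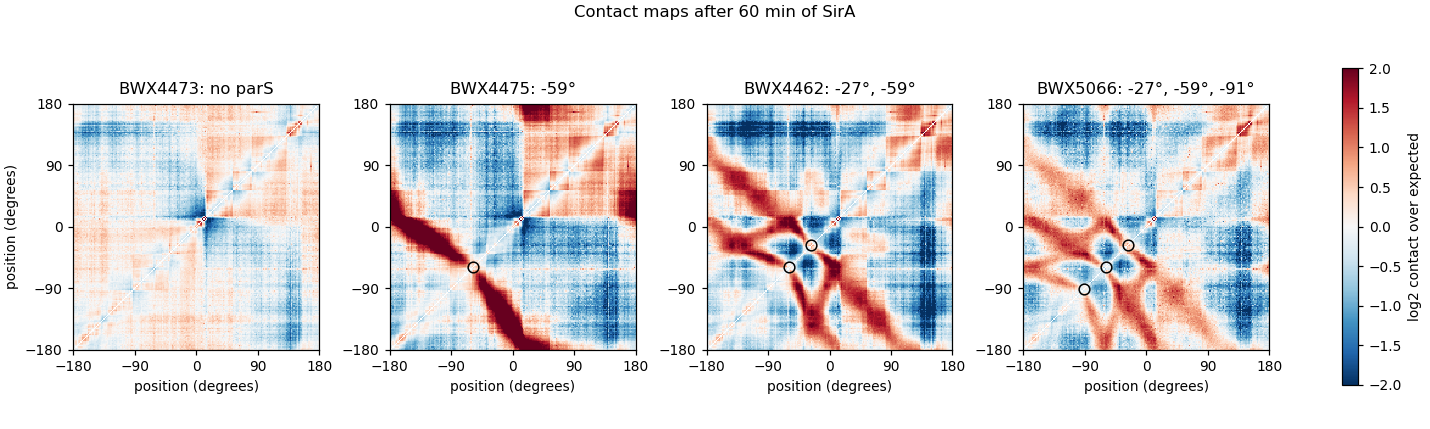
Contact maps after 60 min of SirA for strains with 0, 1, 2 and 3 parS sites, both axes in degrees from the origin, colour showing log2 contact over expected in 20 kb bins and circles marking labelled parS sites. The map of BWX4473 gives 0.29 at -59° when read as a hairpin, and that of BWX4475 has a hairpin from -59° with a strength of 1.65.

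Hairpins were stronger after SirA induction than without it, while a change of their divergence did not pass the test. Across 10 pairs of maps with the same parS sites, mean strength was 1.21 ± 0.22 (SD, n = 10) with 60 min of SirA and 0.80 ± 0.21 without it. It rose in 10 of 10 pairs by 0.40 ± 0.10 (exact two-sided sign-flip permutation test, as for all tests of means below, p = 0.00195, the smallest the design allows, adjusted p = 0.00586). The largest rise was in BWX4462 against BWX4422, from 0.65 to 1.26. Divergence was 0.24 ± 0.10 with SirA and 0.22 ± 0.08 without. The paired difference of 0.02 ± 0.09 (SD, n = 10) was above 0 in 5 pairs, below 0 in 4 and 0 in 1 and did not pass the exact permutation test (p = 0.508, adjusted p = 0.653). In 9 of the 10 pairs the partner without SirA is a separate strain.

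**Figure D2:**
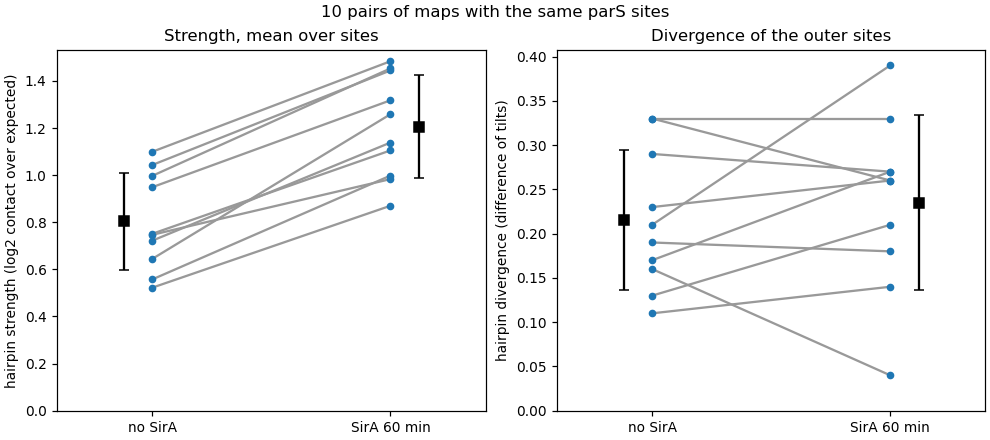
Mean hairpin strength (left, log2 contact over expected) and divergence of the outer sites (right, difference of tilts) in 10 pairs of maps with the same parS sites; lines join a pair, squares and bars give the mean and SD. Strength rose in 10 of 10 pairs, and divergence was higher in 5, lower in 4 and equal in 1.

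The outer hairpins of a strain with several sites differed in tilt, the lower-coordinate one leaning more towards lower coordinates. With 60 min of SirA, divergence was above 0 in 10 of 10 strains, at 0.235 ± 0.099 (SD, n = 10, exact sign-flip permutation test, p = 0.00195, adjusted p = 0.00586). It ranged from 0.04 in BWX4482 (-59° and -117°) to 0.39 in BWX4463 (-59° and -94°). Tilts ran from -0.39 to -0.16 at the lower outer site and from -0.12 to 0.07 at the higher one. Measured from an untilted line, the lower site thus leaned more, and in some strains both hairpins leaned the same way. Measured from the lone sites, which lean themselves, both sites differed. In BWX4463 the tilt was -0.39 against -0.17 alone at -94°, and 0 against -0.12 alone at -59°. In BWX4883 it was -0.24 against -0.05 alone at -91°, and 0.02 against -0.12 alone at -59°. The -0.39, at -94° in BWX4463, lies next to the limit of -0.4. For the 2 strains whose sites were each also mapped alone, divergence was 0.39 in BWX4463 against 0.05 for the lone sites, and 0.26 in BWX4883 (-59° and -91°) against -0.07. Divergence did not pass a test of dependence on spacing, which ran from 291.3 to 1411.7 kb. Pearson's r was -0.51 (permutation p = 0.131, adjusted p = 0.131, n = 10) and Spearman's rho -0.55 (permutation p = 0.103, adjusted p = 0.207), as 1 of 2 relations computed with spacing. Without the 2 strains farthest from the median spacing, r was -0.42. The other relation, of contacts between neighbouring sites with spacing, had r = -0.52 (permutation p = 0.123, adjusted p = 0.131) and rho = -0.17 (permutation p = 0.654, adjusted p = 0.654), and r = -0.01 without the 2 farthest strains, on which its r rested.

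Loci flanking a pair of parS sites contacted each other along the pair's midpoint line more than in the background maps. Over the 300 kb past 2 times the spacing, contacts along the midpoint line exceeded those of the background maps by 0.79 ± 0.41 log2 (SD, n = 8), with 8 of 8 strains higher (exact permutation test, p = 0.00781, adjusted p = 0.0176). The value was 1.35 in BWX4462 (-27° and -59°), where the line stood at 1.31 and the 4 background maps at -0.25 to 0.26. It was 0.28 in BWX4892 (-91° and -117°), where a background map reached 2.11 and the strain 1.30. The excess is over the mean of the background maps: the highest of them lay above the strain's own line in 7 of 10 pairs of sites, and only BWX4462 and BWX4482 (-59° and -117°) exceeded every background map at all their pairs.

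Neighbouring parS sites contacted each other less than the same loci did in maps without the pair. The difference was -1.24 ± 0.18 log2 (SD, n = 10), with 10 of 10 strains lower (exact permutation test, p = 0.00195, adjusted p = 0.00586). It ranged from -1.49 in BWX4892 to -1.00 in BWX5066 (-27°, -59° and -91°). Every pair of sites lay below the lowest of its background maps, but the size of the difference rests on their mean. In BWX4480 (-27° and -117°), with a difference of -1.41, the pair read -0.91 and the background maps ran from -0.62 to 2.93.

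Beyond its partner, a site's own antidiagonal had fewer contacts on average than in the map with that site alone, and this failed the correction. The mean difference was -0.74 ± 0.72 log2 (SD, n = 8), lower in 6 of 8 strains (exact permutation test, p = 0.0312, adjusted p = 0.0563). In strains with 2 sites, the 4 lower-coordinate sites measured had values from -1.61 to -1.20. The 4 higher-coordinate sites had values from 0.08 to 0.36, and this contrast was not tested. In BWX4927, with 3 sites (-59°, -91° and -117°), the highest-coordinate site had -0.29. The -59° site shows both, with -1.61 beside a partner at -27° and 0.27 beside a partner at -94°. The reading follows the untilted antidiagonal. In the strains with 2 sites, the lower sites measured had tilts of -0.39 to -0.20 and the higher ones -0.12 to 0.02. Fewer contacts at the lower sites thus cannot be told apart from hairpins that lean out of the band.

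Time after the block was followed to 120 min in 8 strains, including the wild-type parS set of BWX4359, which was read at -1°. BWX5132 is also among them, and in it IPTG induces additional smc and scpAB, so its times are also times of that induction. The mean difference of strength between 120 and 60 min was -0.035 ± 0.43 log2 (SD, n = 8), above 0 in 7 of 8 strains (exact permutation test, p = 1, adjusted p = 1). The value rests on BWX4359, whose reading went from 0.66 to -0.40, and its sign also turned after division by the map without parS (0.040) and with separations of 60 to 250 kb (0.020). Without BWX4359, 1 of the planned omissions of each strain in turn, singled out after the data were seen, strength rose by 0.11 in the other 7 strains, with 7 of 7 higher (exact permutation test, p = 0.0156, adjusted p = 0.0281). Without BWX5066 as well, it was 0.066 in the remaining 6 (exact permutation test, p = 0.0312, adjusted p = 0.0469). BWX4359 was the only strain that fell, so its omission by itself gives both of these tests the smallest p possible. The 7 strains did not rise steadily: their mean strength was 1.21, 1.38 and 1.32 at 60, 90 and 120 min, and 5 of 7 were lower at 120 than at 90 min. In BWX5066 the outer sites went from 0.99 to 1.73 at -27° and from 0.74 to 1.36 at -91°, while the middle site at -59° went from 0.88 to 1.08 at 90 min and 0.69 at 120 min. Divergence differed by -0.022 ± 0.057 (SD, n = 5), below 0 in 3 of 5 strains (exact permutation test, p = 0.375, adjusted p = 0.562), in a design whose smallest p is 0.0625. The only value above 0 was 0.06 in BWX5132, and without this strain the mean was -0.0425. The difference of divergence was 0.012 after division by the map without parS.

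The strain with additional smc and scpAB, which encode the condensin subunits, had lower hairpin strengths at -59° than the strain without them at each of 3 times. In BWX5132, with sites at -27° and -59° and these genes under IPTG control, the -59° hairpin had a strength of 0.76, 0.33 and 0.33 at 60, 90 and 120 min. In BWX4462, with the same sites, it was 1.37, 1.47 and 1.24. The map without parS gave 0.29 there. At -27° the values were 1.14, 1.52 and 1.67 with the extra genes and 1.15, 1.38 and 1.39 without them. Each time point compares 2 libraries, so the differences have no replicate check. The BWX5132 maps at 90 and 120 min were the sparsest of the series, with 7.28% and 0.83% of pixels at 0, against 0.0050% at 60 min and at most 0.34% in any map of another strain.

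Hairpins were absent before ParB induction and reached farther at later times after it. In these strains SirA was induced with 0.5% xylose for 30 min and ParB then with 1 mM IPTG. Before IPTG, hairpin strength was 0.06 at -59° in BWX4491 and -0.02 at -94° in BWX4492. At 10 min it was 0.83 and 0.67, and at 30 min 1.62 and 1.47. With both sites in BWX4493, strength at 30 min was lower, at 1.23 for -59° and 1.00 for -94°. The planned reading of the front gave 0 kb at 10 and 15 min in every course and 0 kb at all times for -94°, so its slopes of 49.5 ± 15.9 kb/min (SE, 5 times) in BWX4491 and 50.3 ± 15.8 kb/min at -59° in BWX4493 are jumps from 0 and give no usable rate. The ridge traced from its strongest point, a reading chosen after the maps were seen, had its front at a separation of 590 kb at 10 min, 1200 kb at 15 min and 1790 kb at 20 min in BWX4491, with a threshold of log2 of 1. The slope per leg was 60.0 ± 0.6 kb/min (SE, 3 times) in BWX4491 and 46.7 ± 6.0 kb/min (SE, 4 times) in BWX4492. In BWX4493 it was 40.5 ± 2.0 kb/min at -59° and 49 ± 15.6 kb/min at -94° (SE, 3 times each). The windows of 250 kb around these 2 sites overlap, so either trace could follow contacts of the other site. At 25 min, a time left out of the slopes, the midpoints lay -200 kb from -59° and 190 kb from -94°. Both shifts point towards the other site. The lone -59° site of BWX4491 also had -200 kb at 25 min, so that shift is no sign of the other site. The lone -94° site of BWX4492 had 10 kb. As the windows overlap, the 2 slopes in BWX4493 cannot be taken as separate rates of each site. At positions without parS, 60° and 120°, no front passed the threshold of log2 of 1 at any time. With a threshold of 0.5 the slopes were 67, 65, 39.5 and 65 kb/min in the same order, the first 2 from 2 times each, and the same 2 positions without parS passed this threshold at later times, from 20 min in BWX4493. Whether strains differ was not tested.

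**Figure D3:**
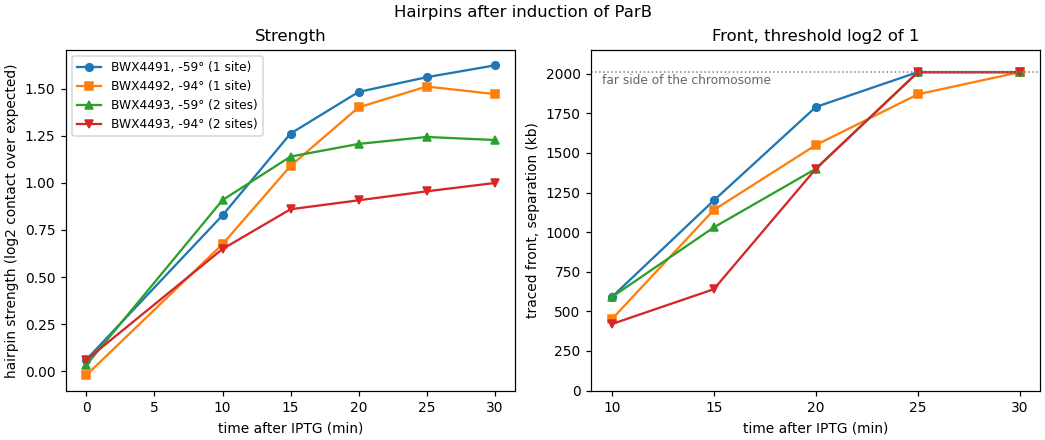
Hairpin strength (left, log2 contact over expected) and traced front (right, separation in kb, threshold log2 of 1) against minutes after IPTG, 1 map per point. Strength at -59° went from 0.06 to 1.62 in BWX4491, and its front moved from 590 kb at 10 min to 1790 kb at 20 min.

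An (XDS)12 array was placed at -109°, -80° or -19° in 5 strains with parS at -27°, -59° or -94°. The planned measure, the drop of the nearest hairpin past the array, differed from the strain without the array by -0.11 ± 0.45 log2 (SD, n = 5, exact permutation test, p = 0.688, adjusted p = 0.773, smallest p 0.0625), below 0 in 3 of 5 pairs. Without BWX4520 it was 0.013, and 3 of the 5 pairs share a control map. Further measures chosen after the maps were seen described the hairpin itself. Strength at the site nearest the array was lower in 5 of 5 pairs, by -0.65 ± 0.44 on average (exact permutation test, p = 0.0625, the smallest possible). The change was -1.22 at 90 kb from the array (BWX4520, -27°), -0.93 at 168.1 kb (BWX4509, -94°), -0.64 at 235.3 kb (BWX4519, -59°), and -0.22 at 560 kb in both BWX4507 and BWX4508 (-59°). The sites farther from the array in the same strains had 0.01 at 448 kb (BWX4520, -59°), -0.08 at 560 kb (BWX4509, -59°), 0.25 at 594 kb (BWX4519, -27°) and -0.15 at 919 kb (BWX4508, -27°). At the nearest site of BWX4520 and BWX4509 strength was -0.07 and -0.16, below the 0.36 and -0.01 of the map without parS. Contacts joining the 200 kb on either side of the array were lower by 0.63 to 0.95 log2 in the 4 strains with arrays at -109° or -80° and higher by 0.09 with the array at -19° (exact permutation test over 5 pairs, p = 0.125). The last value depends on the window, at -0.02 with 100 kb and -1.00 with 400 kb.

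**Figure D4:**
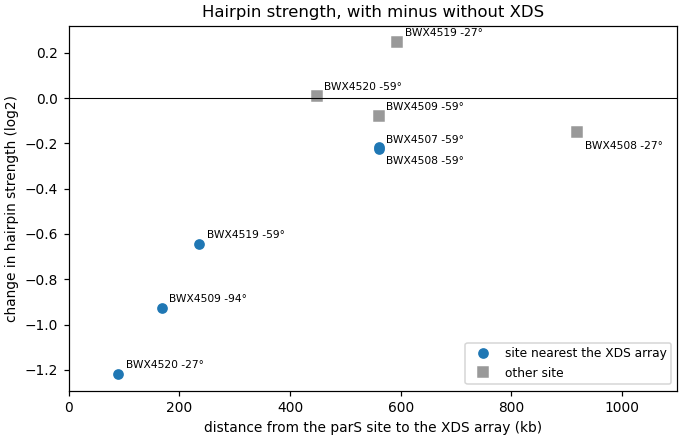
Change in hairpin strength (log2, strain with the array minus strain with the same parS sites and no array) against the distance from each parS site to the array in kb. The nearest sites run from -1.22 at 90 kb to -0.22 at 560 kb. At 90 and 168.1 kb an untilted line runs past the array within the separations read.

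SMC ChIP was higher between parS sites than in their flanks in all 6 libraries with SirA. In BWX4462 the stretch between -59° and -27° exceeded its flanks by 0.71, 1.1 and 1.1 log2 of ChIP over input at 60, 90 and 120 min. In BWX5066 the stretches between -91° and -27° exceeded theirs by 0.71, 1.1 and 1.05. These are values of 1 library each, with no test. At parS itself, enrichment over 20 kb at -59° was 0.99, 1.45 and 1.71 in BWX4462 and 1.01, 1.18 and 2.51 in BWX5066, where this is the middle site. At -27° it was 1.53 at 60 min and 1.38 at 120 min in BWX4462, and 1.03 and 1.23 in BWX5066, whose -91° site had 1.12 and 0.83. Over the 5 sites the change was 0.40 ± 0.73 (SD, n = 5), higher at 3 of 5 (exact permutation test, p = 0.375, smallest p 0.0625), and sites of a strain share a library. It depended on the scaling: with coverage scaled to the genome median it was 0.90 ± 0.73, higher at 5 of 5 sites (exact permutation test over sites, p = 0.0625, which treats the sites of 2 strains as independent). Scaling to the median shifts all sites of a strain by nearly the same amount, so 5 of 5 is not agreement between separate sites. With 4 kb around the position computed from the degrees the change was 0.27 ± 0.74, higher at 2 of 5. The ParB maxima of BWX4462 at -27° and -59° lay -4.45 kb and 6.08 kb from those positions. The 4 kb windows miss them, so this value does not give the change at parS. Without SirA, BWX3370 had 1.68 at its -1° site.

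**Figure D5:**
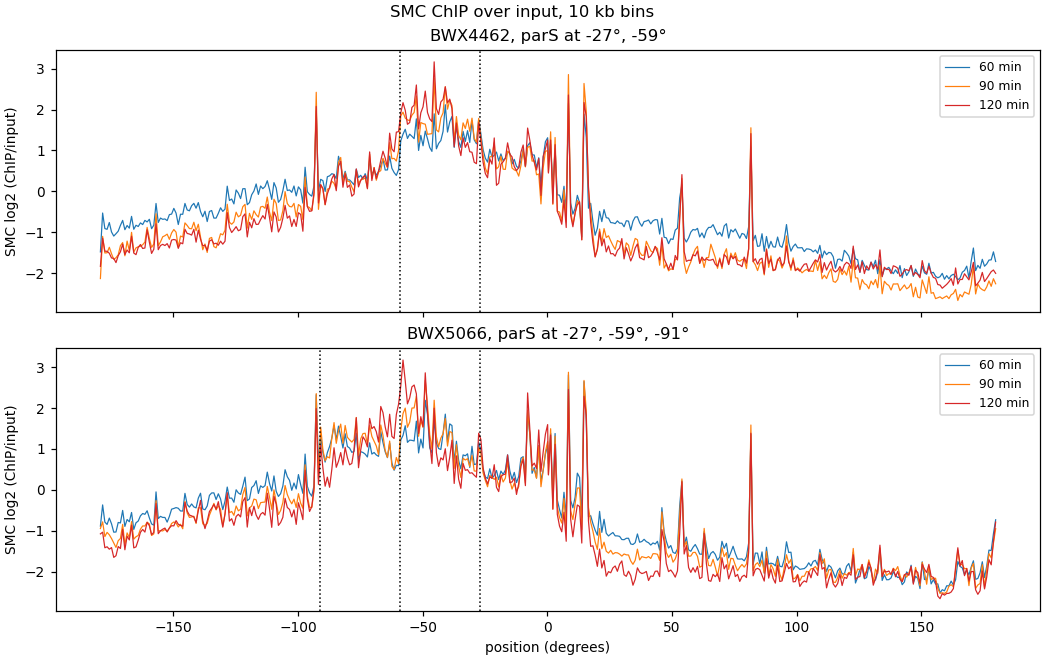
SMC ChIP over input (log2, means of 10 kb bins) against position in degrees in BWX4462 and BWX5066 at 60, 90 and 120 min of SirA, with dotted lines at parS sites. Enrichment over 20 kb at -59° went from 0.99 to 1.71 in BWX4462 and from 1.01 to 2.51 in BWX5066.

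Away from the parS sites of the strains with SirA, the 10 highest 1 kb bins of SMC ChIP formed 9 regions with mean enrichments of 2.95 to 3.82 log2 over the 6 SirA libraries, against a genome median of -1.01. The region with the highest value was 915001 to 916000, at 3.82 ± 0.30 (SD over 6 libraries of 2 strains). Positions 10001 to 11000, 30001 to 31000, 95001 to 96000, 161001 to 162000 and 598001 to 599000 lay on the right side of the origin at 3.07, 3.08, 2.95, 3.00 and 3.21. These 6 regions were above 2 in BWX3370 as well, at 2.50 to 3.94, in cells without SirA. The first 2 of them, at 10001 and 30001, lie 21.7 and 41.7 kb from the -1° parS that BWX3370 itself carries, so they are away from parS only in the strains with SirA. ParB ChIP of BWX4462 was also raised in all 6, at 0.13 to 0.81 against its genome median of -1.37. Signal in these 6 regions is thus not particular to SMC ChIP. The other 3 lay between -59° and -27°, at 3485001 to 3486000 (2.97), 3525001 to 3527000 (3.14) and 3574001 to 3575000 (3.06), and BWX3370 had -2.24, 1.04 and 1.39 there. ParB ChIP had -1.99, -0.97 and -0.80 at these 3. In the first of these 3 the inputs of BWX5066 were low, at -1.48 log2 of their genome mean against 0.26 in BWX4462, and the ratio was 3.78 in BWX5066 and 2.15 in BWX4462.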

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

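The outward-contact test and the search for the position of the wild-type hairpin were set out before their results were seen, although the maps of the wild-type set had been looked at. The tests on the XDS strains with their bounds, the contact shares with no expected contact and the mean of the other strains were chosen only after the result was seen.

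The hairpin of the wild-type parS set in BWX4359, read at -1°, differed by -1.06 log2 between 120 and 60 min of SirA. Its gap to the nearest other strain was 0.737 of the whole range, the 1 such value in 12 sets of values examined. Chance gives about 1 in 20 in each set, so that a flag somewhere among 12 sets may arise by chance. Some of the sets also share strains and libraries. A general weakening of hairpins is argued against by the other 7 strains, whose mean difference was 0.11. The highest strength found within 40° of the origin differed by 0.60, from 1.06 at -30° to 1.65 at -29°; a line that had merely left the hairpin was set to give a change below 0.5 and a weaker hairpin a fall of 0.5 or more, and the rise met neither, so the test did not decide. The labels give no positions for the parS sites of this strain, a different use of its sites stays open, and no biological explanation was tested.

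In strains with 2 sites, contacts beyond the partner were below those of the map with that site alone at 4 of 4 lower-coordinate sites and above them at 4 of 4 higher-coordinate sites, and the means differed by -1.58 log2. This difference was not tested, and strains with 3 sites are not part of it. The highest-coordinate site of BWX4927, which has 3, was at -0.29, below the map with that site alone. As the band is untilted and the lower-coordinate sites leaned more, fewer contacts there cannot be told apart from hairpins that left the band.

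Neighbouring parS sites contacted each other less than in maps without the pair. An expected contact raised by the hairpins is argued against by contact shares with no expected contact, which differed by -1.41 log2. Bins at parS may also share out a fixed total. Outward contacts, of the same sites over the same distance away from the partner, were compared with this in mind. They were higher than contacts with the partner by 1.03 ± 0.61 log2 (SD, n = 10) in 10 of 10 strains (exact two-sided permutation test, p = 0.00195). This cannot decide the question, because both bins of a partner contact hold parS and a fixed total would lower it more than an outward contact. The outward contacts themselves were at -0.39 ± 0.59 relative to background, and below it in 9 of 10 strains. How much of the lower contact between neighbouring sites comes from the fixed total thus stays open. A biological explanation stays open and was not tested.

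The hairpin at the site nearest an XDS array was missing or weak in 3 of 5 strains. An absent parS site would leave no more strength than in the map without parS, and the differences from that map were -0.14 at -94° in BWX4509 and -0.43 at -27° in BWX4520, so that an absent site or a wrong label may account for these libraries. Their strengths of -0.16 and -0.07 lay within those of maps with neither a site within 10° nor an array. Those were -1.13 to -0.01 in 7 maps at -94° and -0.38 to 0.50 in 9 maps at -27°. At both sites an untilted line also runs past the array within the separations read, so that strength mixes contacts before and past it. At -59° in BWX4519 strength was 0.43 above the map without parS and, at 0.73, above the -0.42 to 0.34 read there in 7 maps with no site near -59°, which argues against an absent site. Correlations between whole maps decide nothing here, since a map with a weak hairpin resembles maps without that site for either reason, and the closest map lacked it for BWX4509 (BWX4507, r = 0.92), BWX4520 (BWX4475, r = 0.89) and BWX4519 (BWX4480, r = 0.68) alike. An effect of the array stays open for all 5 strains, and whether it depends on distance was not tested.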

How the results depend on the processing

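Alternatives were fixed before the data were examined, except the traced fronts, the contact shares with no expected contact, the omission of BWX4359 and BWX5066 together and the further XDS measures, which were chosen after seeing the data. The omission of the wild-type parS set, BWX4359, was planned as 1 of the omissions of each strain and was singled out afterwards. Of the recomputed values, 7 changed sign, 2 of them this same omission counted both ways, 17 moved without a test, and the others kept their direction and side of the threshold or stayed within their spread. The 5 alternatives kept the divergence with SirA at 0.182 to 0.235 and the rise of strength with SirA at 0.31 to 0.40, each with adjusted p = 0.00586 in the exact permutation test; the midpoint line and the contacts between sites kept their calls under all of theirs. These 4 calls also held when each strain was left out in turn.

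The change of strength from 60 to 120 min turned to 0.040 after division by the map without parS, to 0.020 with separations of 60 to 250 kb to 0.11 without the wild-type parS set and to 0.066 without BWX5066 as well; leaving out each strain in turn gave -0.095 to 0.11. The change of divergence from 60 to 120 min turned to 0.012 after division by the map without parS. None of these except the 2 omissions of the wild-type set, alone and with BWX5066, passed the threshold (adjusted p of 0.0281 to 1 over the strength alternatives, exact permutation tests), and the cause was not tested. Those 2 omissions take out the only strain that fell, which fixes their p-values at the smallest possible. The drop past the XDS array lay between -0.26 and 0.013 when each pair was left out, with 0.013 without BWX4520. Contacts across the array differed by -0.51 with windows of 100 kb and -0.93 with 400 kb, below 0 in 5 of 5 pairs under each (exact permutation test, p = 0.0625, the smallest possible).

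Planned fronts depended on the threshold. In BWX4491 the slope was 0 kb/min with a threshold of 1, 32.6 without the 0 min map, 42.6 to 66.5 when each time was left out, and 67 with the front traced at 0.5. In BWX4492 it was 60.3 kb/min with a threshold of 0.25, and 65 and 46.7 with the front traced at 0.5 and 1. At -59° in BWX4493 it was 18.4 kb/min with a threshold of 0.25, 0 with a threshold of 1, 0 without the 0 min map, and 43.4 to 66.4 when each time was left out. At -94° in BWX4493 the traced fronts gave 65 and 49 kb/min, from a window that overlaps that of the -59° site. The cause was not tested; traced fronts at 0.5 leave only 2 or 3 times before the far side of the chromosome.

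Origin to terminus ratios moved to 2.85 in BWX3370, 2.64 in BWX4462 before IPTG and 1.03 in BWX5066 at 120 min with windows of 200 kb, and to 2.83 in BWX4462 before IPTG with the terminus at 180°. The change of SMC enrichment at parS from 60 to 120 min was 0.40, higher at 3 of 5 sites. Scaled to the genome median it was 0.90, higher at 5 of 5 sites, which come from 2 strains and share libraries. Scaling to the median shifts all sites of a library by nearly the same amount, set by its mean coverage over its median. From 60 to 120 min the SMC ChIP mean went from 24.5 to 20.2 and the median from 16 to 9 in BWX4462. In BWX5066 the mean went from 27.5 to 23.8 and the median from 16 to 10. The higher change with the median thus comes from a shift shared by the sites of each strain. With 4 kb around the positions computed from the degrees the change was 0.27, higher at 2 of 5. Those windows miss the ParB maxima of BWX4462, so 0.27 does not give the change at parS. SMC between sites stayed above the flanks with 50 kb around sites left out and without input. Median and no-input readings over gene lists were not run, for want of an annotation on the build of the files. Depth limits the coverage tracks, with a mean of 12.0 and a median of 4 reads per base for ParB, and the depth of the maps is unknown.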

Other observations

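All values in this part were chosen after the maps and tracks were seen. Contacts across a position to the right of the origin were low in the maps with and without parS. Contacts joining the 200 kb on either side of 14.7° had a mean log2 contact over expected of -1.31 over 36 maps with parS and at least 60 min of SirA, the lowest mean of any position, with a range of -2.07 to -0.32 over these maps, and -1.44 in the map without parS. SMC ChIP over input fell by 0.88 ± 0.31 (SD over 6 libraries) across 19.4°, as the median of the 100 kb above minus the 100 kb below, and by 1.15 ± 0.22 across 1.43°. In BWX3370, without SirA, the steps at these positions were -0.02 and -0.82. The SMC bin at 161001 to 162000 lies in the 10 kb bin of the first position. Steps up towards higher coordinates were 0.83 ± 0.23 at 3370 kb, next to the -59° site, 0.82 ± 0.23 at 1988 kb (177.4°), near no labelled parS, and 0.78 ± 0.40 at 3009 kb, next to the -91° position. The last was 1.11 on average in BWX5066, which carries parS there, and 0.46 in BWX4462, which does not.

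Inputs differed in evenness between strains. Those of BWX5066 are labelled rep2 and those of BWX4462 are not, so strain cannot be told apart from replicate here. The share of 1 kb bins below a log2 of -1 relative to the library mean was 0% in the 3 SirA inputs of BWX4462 and 0.62%, 0.79% and 2.78% at 60, 90 and 120 min in BWX5066. It was 2.16% in BWX3370 and 0.12% in BWX4462 before IPTG, whose coverage differed between origin and terminus. Log2 ratios at such bins in BWX5066 divide by a low input, as at 3485001 to 3486000.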
